A study of Homo sapiens with 12 samples.

How the data were processed

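The samples were human monocyte-derived macrophages on 12 arrays, in 4 groups of 3. Per the labels' protocols, CD14-positive monocytes were kept for 7 days with 25 ng/ml of M-CSF, the growth factor that turns monocytes into macrophages. Untreated cells were compared with cells given manganese chloride (Mn) at 25 µM, cells transfected with DNA, and cells that received DNA by transfection after 24 h of Mn (Mn+DNA). RNA of the transfected cells was taken 24 h after the transfection. No such time is recorded here for untreated cells or cells given Mn alone, nor whether Mn stayed on after the 24 h. A difference in harvest time or Mn exposure can therefore not be told apart from the effect of DNA, nor from the interaction of Mn and DNA. The labels give each group the same replicate numbers, 1 to 3, and tie each number to 1 donor. A group that received the transfection reagent without DNA was not analysed here, so the DNA comparisons hold the transfection together with the DNA. The labels name neither the sequence nor the amount of the DNA. Replicates came from separate donors.

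Per the labels, biotin-labelled cRNA was made from 100 ng of total RNA and hybridised to Affymetrix whole-transcript arrays. The deposited table held log2 values made with RMA and Partek, per the submitters' processing notes, which give no versions in the sources used here. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each row into 1 log2 signal. The table had 53617 rows and no missing value. Array medians lay between 3.13 and 3.20 and array means between 4.00 and 4.01, so the deposited values had already been brought to a common scale. RMA gives no detection call. A signal near the floor of the scale therefore does not show whether a transcript was present, and fold changes of genes near the floor or the ceiling are understated. The lowest value in the table was 1.12 and the highest 13.69. For arrays there is no read depth, and the number of arrays limits the precision.

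Rows were named through the platform annotation supplied with the values, with symbols updated by gene ID from a RefSeq gene table. A single symbol was found for 16098 rows, several symbols for 0 rows, and 37519 rows had no name here. All 16098 named rows matched the gene table by ID, and they carried 14884 distinct symbols. Of the rows of 1 gene, the one with the highest mean over all arrays was kept, which concerned 778 genes. Y-linked genes, XIST and TSIX were left out because the samples came from donors. The test covered 14873 genes, 11909 of them protein-coding. No filter on signal was applied. No coordinates are given, because no genome build was used.

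Genes were tested with limma 3.58.1 in R 4.3.3. All 12 arrays entered 1 linear model with a mean per group and no donor term, followed by eBayes, two-sided tests and Benjamini-Hochberg adjustment over the 14873 genes. The model had 8 residual degrees of freedom and 4.22 prior degrees of freedom. A gene was called changed at an adjusted p under 0.05. The comparisons were DNA against untreated, Mn against untreated, Mn+DNA against DNA, Mn+DNA against Mn, Mn+DNA against untreated, and the interaction. The interaction is the change from Mn to Mn+DNA minus the change from untreated to DNA. Errors of log2 changes are standard errors (SE) from this model, over 3 arrays per group.

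Before the data were examined, 33 gene lists were fixed, along with the design, the other settings to be tried and the rule for the genes to be named. The lists covered type I and III interferons, interferon-stimulated genes, guanylate-binding and interferon-gamma-inducible genes, MHC class I and class II presentation, inflammatory cytokines and chemokines, NF-kB feedback genes, cytosolic nucleic acid sensing, inflammasome and pyroptosis, manganese transport, metallothioneins and zinc transport, iron handling, the oxidative stress response, the unfolded protein and integrated stress response, and heat shock proteins. They also covered cholesterol synthesis, cholesterol efflux and LXR targets, glycolysis and hypoxia, oxidative phosphorylation, lysosome, alternative activation and tissue macrophage markers, phagocytosis and Fc receptors, cell cycle, and p53 targets and apoptosis. Markers of other cell types completed them: monocyte, T cell, NK cell, B cell, neutrophil, platelet, erythroid, dendritic cell, and fibroblast and endothelial. Together they held 347 measured genes. Lists with at least 3 measured members were tested with camera from limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. This left 31 lists. None of the 21 type I and III interferons was named in the probe table, and 1 erythroid marker was measured. Counts of list members adjusted over all genes are given beside those adjusted over the list alone.

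The genes named per comparison are the 8 with the largest rise and the 8 with the largest fall among those past the threshold that moved the same way in 3 of 3 donors. To these come up to 4 members of each described list, those with the smallest unadjusted p. CXCL10, TNF, CGAS, STING1, TBK1, MT1X, MT2A and HMOX1 were always to be given. IFNB1, IFNL1, IL6, SLC30A10, SLC39A8, SLC39A14, SOD2 and TFRC were on the same list but were not named in the probe table, so they are not analysed here. Uncharacterised, small RNA, olfactory receptor and pseudogene symbols were counted and not named. A list member named beyond these was chosen after its values were seen.

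Whether the replicate numbers pair the samples was checked from the deviations of each array from its group mean. Arrays of the same number correlated at 0.175 to 0.365 (median 0.274, 18 pairs), and arrays of different numbers at -0.273 to 0.006 (median -0.128, 36 pairs). The numbers therefore pair the samples, as the donor labels state. The fit with the replicate number as a block was one of the other settings. The remaining ones were a fit on the compared groups alone, eBayes with trend and robust settings, array weights, a filter on dim genes, every named row tested, the mean of a gene's rows, median centring, a second quantile normalization, and leaving out each array and each replicate number. Lists were also tested with an estimated inter-gene correlation. Within groups, pairs of arrays correlated at 0.981 to 0.986 across all rows.

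The test was tried on simulated data over the same 14873 genes, with 66 or 67 genes changed at each fold size. A 4-fold change was recovered for 97.0% of genes in DNA against untreated and 97.0% in Mn against untreated, and a 2-fold change for 76.1% in each. In Mn+DNA against DNA the shares were 98.5% at 4-fold and 80.6% at 2-fold, in Mn+DNA against Mn 100% and 80.6%, and in Mn+DNA against untreated 100% and 76.1%. The interaction recovered 89.4% at 4-fold and 41.8% at 2-fold. Genes called without a simulated change made up 3.19% to 10.7% of calls, the highest share in Mn+DNA against untreated. With no simulated change at all, limma called 0 genes in each of the 6 comparisons. The simulated noise was independent between genes and held no donor effect, unlike the real arrays. Far fewer genes were changed in it than were called in the real comparisons of group pairs. The rates in the real data may therefore differ. After the data had been examined, a fit of every row of the table, named or not, and a second quantile normalization for the gene lists were added. After the results of the fixed lists were known, further targets of ATF4 and of HIF-1, 28 genes each, were listed before their own values were looked at. Also after seeing the data, 17 gene families were picked by symbol, and the 11 with at least 3 measured members were tested with camera and adjusted over those 11. Figures were drawn with matplotlib.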

Results

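Transcript levels were measured on 12 whole-transcript arrays of human monocyte-derived macrophages, with 3 untreated arrays, 3 after Mn, 3 after DNA transfection and 3 after Mn followed by DNA (Mn+DNA). Each group held the same 3 donors. The design asked how Mn pretreatment changed the macrophages and how it changed their response to transfected DNA, a stimulus of the cytosolic DNA sensor CGAS and its partner STING1. Values were log2 signals, and the 14873 tested genes had array medians of 4.29 to 4.35. Log2 changes are given with their SE, and each group mean rests on 3 arrays.

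The largest rises after DNA transfection were in CXCL9, CXCL10 and CXCL11, interferon-inducible chemokines that recruit activated T cells. They rose by 9.0 ± 0.25, 8.68 ± 0.65 and 8.45 ± 0.28 on the log2 scale, or 512-, 410- and 351-fold. The ectoenzyme CD38 rose by 6.88 ± 0.29, the monocyte attractant CCL8 by 6.71 ± 0.68, the DNA-binding inflammasome sensor AIM2 by 6.04 ± 0.22, PDGFRL by 6.02 ± 0.21 and CCL5 by 5.77 ± 0.26. The largest falls were in the receptor GPR34 (-5.33 ± 0.75), MANSC4 (-4.50 ± 0.18), SESN3 (-4.35 ± 0.46), the pantetheinase VNN1 (-4.28 ± 0.42), CD180 (-3.99 ± 0.55), the scavenger receptor COLEC12 (-3.71 ± 0.36), RGS18 (-3.61 ± 0.32) and hepatocyte growth factor HGF (-3.54 ± 0.30). All of these moved the same way in 3 of 3 donors, with limma adjusted p of 0.000407 or less. In total 946 genes were higher and 1196 lower in DNA than in untreated cells, and 379 and 293 of them changed at least 2-fold. Without DNA replicate 3 the lower genes numbered 772.

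Of 38 measured interferon-stimulated genes, 37 rose after DNA and none fell (38 and 0 adjusted over the list alone), with a median log2 change of 2.96. IFITM1 rose by 5.25 ± 0.22, RTP4 by 3.79 ± 0.17, and the RNA sensors RIGI and IFIH1 by 3.06 ± 0.14 and 2.98 ± 0.15. IFITM1 has close paralogs, so its value is uncertain. Among 14 guanylate-binding and interferon-gamma-inducible genes, 12 rose (14 adjusted over the list alone), including CD274, the ligand of PD-1, by 3.64 ± 0.18 and the GTPase GBP4 by 4.99 ± 0.36. The camera adjusted p was 5.32e-56 for the first list and 9.09e-22 for the second, and 0.0483 for each with an estimated correlation. Of the DNA-sensing machinery, CGAS rose by 2.30 ± 0.25 (adjusted p = 6.54e-05) and the kinase TBK1 by 1.03 ± 0.13 (adjusted p = 0.000217), while STING1 differed by 0.16 ± 0.15 (adjusted p = 0.603). The metallothionein MT2A rose by 2.05 ± 0.20 (adjusted p = 2.54e-05), MT1X differed by -0.23 ± 0.31 (adjusted p = 0.745) and HMOX1 by 0.03 ± 0.17 (adjusted p = 0.954). In the cytosolic nucleic acid sensing list, 8 of 20 rose and 2 fell (8 and 3 adjusted over the list alone), with AIM2 and the RNA sensor TLR3 (3.24 ± 0.25) in front. Its camera adjusted p was 0.0105, and the adjusted p was 0.245 with an estimated correlation.

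Some inflammatory genes rose after DNA as well. Of 21 cytokines and chemokines 6 rose (8 adjusted over the list alone), among them CCL5, CCL8, CCL2 (2.18 ± 0.26) and the interleukin-1 receptor antagonist IL1RN (4.56 ± 0.26), and TNF rose by 1.27 ± 0.23 (adjusted p = 0.00233). Of 10 NF-kB feedback genes 6 rose (6 adjusted over the list alone), with TRAF1 at 2.66 ± 0.20, NFKB2 at 1.16 ± 0.11, RELB at 1.07 ± 0.11 and ICAM1 at 1.20 ± 0.19. The camera adjusted p was 2.38e-06 for the cytokines and 7.57e-05 for the NF-kB genes. With an estimated correlation the adjusted p was 0.0692 and 0.0722. The MHC class II presentation list moved (adjusted p = 0.00999) through its costimulatory ligands, CD80 (3.85 ± 0.24) and CD86 (0.57 ± 0.11), which were 2 of its 4 measured genes (3 adjusted over the list alone), and its adjusted p was 0.0722 with an estimated correlation. Of 4 inflammasome and pyroptosis genes, the membrane-rupture protein NINJ1 (1.37 ± 0.16) and the pore former GSDMD (0.85 ± 0.13) rose (adjusted p of the list = 0.00228; adjusted p = 0.0692 with an estimated correlation; 2 adjusted over the list alone). Of 10 genes on the manganese transport list 3 were measured, and the P5-type ATPases ATP13A1 (0.84 ± 0.11) and ATP13A2 (1.01 ± 0.26) rose (3 adjusted over the list alone). The camera adjusted p of the list was 0.00523, and 0.0692 with an estimated correlation. SLC30A10, SLC39A8 and SLC39A14 of this list were not measured, so it does not speak for manganese transport as a whole. TMEM165 differed by 0.44 ± 0.15 (adjusted p = 0.0744, or 0.0381 with the donor as a block).

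After DNA, 8 of 15 genes of the unfolded protein and integrated stress response list fell and 1 rose (8 and 2 adjusted over the list alone). The mTOR inhibitor DDIT4 changed by -1.59 ± 0.22, the ER-degradation component SEL1L by -0.74 ± 0.11, the pseudokinase TRIB3 by -1.29 ± 0.19 and asparagine synthetase ASNS by -1.21 ± 0.18. Of 23 cell cycle genes 4 fell and 2 rose (7 and 2 adjusted over the list alone). MKI67 (-2.22 ± 0.34), TOP2A (-1.71 ± 0.23) and the helicase subunit MCM6 (-1.57 ± 0.19) fell, and PCNA rose by 0.99 ± 0.20. Of 16 alternative activation and tissue macrophage markers 4 fell and none rose (4 and 1 adjusted over the list alone): MERTK, a receptor for apoptotic cells (-1.69 ± 0.15), the complement receptor VSIG4 (-1.80 ± 0.23), the scavenger receptor STAB1 (-1.68 ± 0.37) and the transcription factor MAF (-1.48 ± 0.34). In the p53 and apoptosis list 4 of 11 rose and 2 fell (6 and 2 adjusted over the list alone), with the necroptosis effector MLKL at 1.67 ± 0.22, PMAIP1 at 1.37 ± 0.34, BAX at 0.55 ± 0.14 and TP53INP1 at -1.09 ± 0.25. The camera adjusted p of these 4 lists was 0.00523, 0.0105, 0.0246 and 0.0246. With an estimated correlation the adjusted p was 0.379, 0.222, 0.165 and 0.41.

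**Figure D1:**
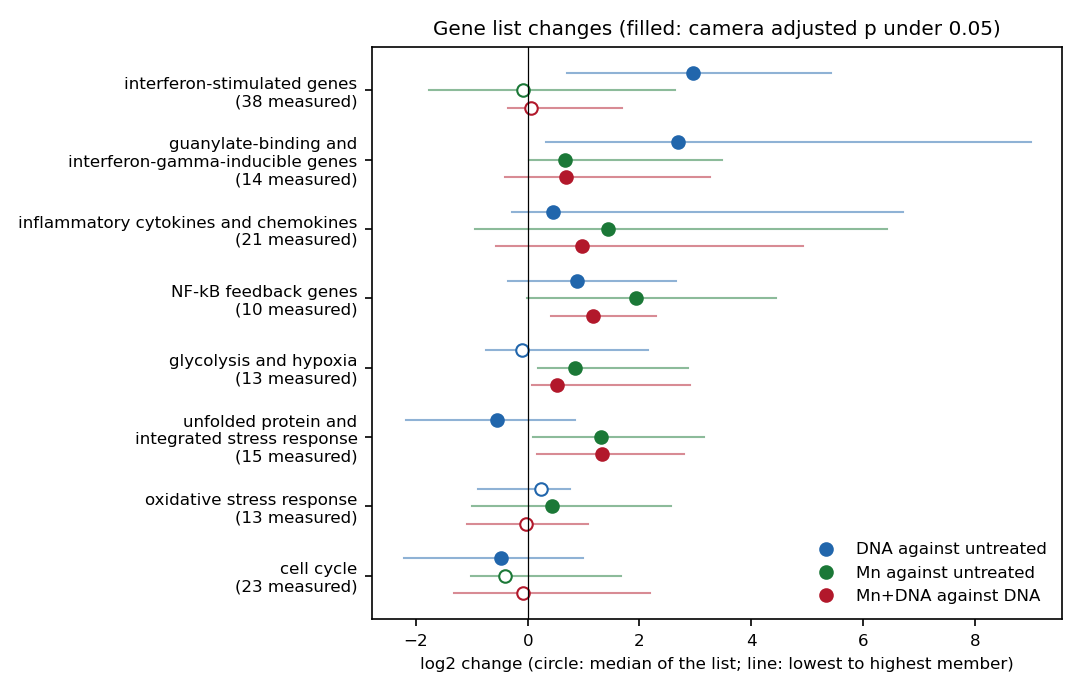
Median log2 change (circles, x axis) of 8 gene lists fixed beforehand, in DNA against untreated (blue), Mn against untreated (green) and Mn+DNA against DNA (red), with lines from the lowest to the highest member; filled circles mark lists with a camera adjusted p under 0.05. The interferon-stimulated genes stand at 2.96 after DNA, at -0.09 after Mn and at 0.06 for Mn+DNA against DNA, while the NF-kB list stands at 0.89, 1.94 and 1.17.

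The largest rises with Mn alone were in a pair of chemokines. The neutrophil attractant CXCL8 rose by 6.42 ± 0.44 (85.9-fold) and CCL4, an attractant of monocytes and T cells, by 5.93 ± 0.76 (61-fold). The sphingosine-phosphate phosphatase SGPP2 rose by 5.14 ± 0.33, the interleukin-7 receptor IL7R by 5.12 ± 0.44, the amplifying receptor TREM1 by 4.84 ± 0.26, F2RL2 by 4.61 ± 0.58, TRAF1 by 4.45 ± 0.20 and CCL3L1 by 4.38 ± 0.44. CCL3L1 and CCL4 have near-identical copies that the array may not tell apart. The largest falls were GPR34 (-4.87 ± 0.75), HGF (-4.76 ± 0.30), MANSC4 (-4.15 ± 0.18), RGS18 (-3.99 ± 0.32), the myeloid nuclear protein MNDA (-3.70 ± 0.13), the endosomal RNA sensors TLR7 (-3.69 ± 0.60) and TLR8 (-3.01 ± 0.28), and the adaptor SCIMP (-3.67 ± 0.24). Each moved the same way in 3 of 3 donors, with limma adjusted p of 0.00137 or less. In total 1038 genes were higher and 1105 lower in Mn than in untreated cells, and 318 and 276 of them changed at least 2-fold.

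Of 21 inflammatory cytokines and chemokines, 15 rose with Mn and 1, IL10, fell by 0.95 on the log2 scale (18 and 1 adjusted over the list alone). TNF rose by 3.61 ± 0.23 and PTGS2, the inducible enzyme of prostaglandin synthesis, by 3.70 ± 0.26, and CCL5 rose by 3.30 ± 0.26. Of 10 NF-kB feedback genes 9 rose (9 adjusted over the list alone), led by TRAF1, NFKB2 (2.12 ± 0.11), RELB (1.51 ± 0.11) and TNIP1 (2.03 ± 0.16). Of 13 glycolysis and hypoxia genes 11 rose (12 adjusted over the list alone). The mitophagy receptor BNIP3 rose by 2.87 ± 0.14, the angiogenic factor VEGFA by 2.02 ± 0.10, adrenomedullin ADM by 2.80 ± 0.15 and hexokinase HK2 by 1.5 ± 0.10. Camera gave these lists adjusted p of 5.94e-15, 3.54e-14 and 1.54e-16, and 0.00867, 0.00867 and 0.000979 with an estimated correlation.

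The stress response list rose with Mn, with 12 of 15 members higher and none lower (13 adjusted over the list alone). DDIT4 rose by 2.56 ± 0.22, the lipoprotein receptor VLDLR by 3.16 ± 0.27, ASNS by 2.00 ± 0.18 and the transcription factor ATF3 by 1.81 ± 0.19 (list adjusted p = 1.88e-13; adjusted p = 0.0637 with an estimated correlation). Oxidative stress genes went both ways, with 6 of 13 higher and 2 lower (7 and 3 adjusted over the list alone). The thioredoxin pathway genes SRXN1 (2.56 ± 0.19), TXNRD1 (1.44 ± 0.15) and TXN (0.94 ± 0.11) rose, and catalase CAT (-0.99 ± 0.12) and heme oxygenase HMOX1 (-0.86 ± 0.18) fell. That list had an adjusted p of 0.00478, and an adjusted p of 0.129 with an estimated correlation. Of 7 phagocytosis and Fc receptor genes, the scavenger receptor MARCO (-1.91 ± 0.20), the lipopolysaccharide co-receptor CD14 (-1.44 ± 0.18) and TREM2 (-0.85 ± 0.21) fell and none rose (3 adjusted over the list alone, 1 higher and 4 lower with the donor as a block; list adjusted p = 0.015; adjusted p = 0.168 with an estimated correlation). The lipopolysaccharide receptor TLR4 differed by -0.51 ± 0.23 (adjusted p = 0.178, or 0.0204 with the donor as a block). Among the metal-binding metallothioneins, MT2A fell by 0.98 ± 0.20 (adjusted p = 0.00587), and MT1X differed by -0.77 ± 0.31 (adjusted p = 0.133, or 0.0275 with the donor as a block).

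Interferon-stimulated genes as a list did not pass the test with Mn alone. Of 38, 7 rose and 4 fell (8 and 6 adjusted over the list alone, 8 and 9 with the donor as a block), with a median of -0.09 and a camera adjusted p of 0.953. Within the guanylate-binding and interferon-gamma-inducible list 3 of 14 rose (4 adjusted over the list alone, 5 with the block): CD274 by 3.47 ± 0.18, the transcription factor IRF1 by 1.73 ± 0.22 and WARS1 by 0.68 ± 0.15. Its adjusted p was 8.88e-05, and 0.261 with an estimated correlation. CXCL10 differed by 1.51 ± 0.65 (adjusted p = 0.167, or 0.0497 with the donor as a block). CGAS rose by 0.94 ± 0.25 (adjusted p = 0.0271) and TBK1 by 0.80 ± 0.13 (adjusted p = 0.00151), and STING1 differed by -0.35 ± 0.15 (adjusted p = 0.154). Of 20 cytosolic nucleic acid sensing genes 4 rose and 5 fell (5 and 5 adjusted over the list alone; list adjusted p = 0.48). Alternative activation markers had 5 of 16 lower and 1 higher (5 and 1 adjusted over the list alone), with a list adjusted p of 0.0756, or 0.0312 with the donor as a block. MHC class I presentation had 1 of 6 higher (1 adjusted over the list alone), with a list adjusted p of 0.1, or 0.0469 with the block.

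**Figure D2:**
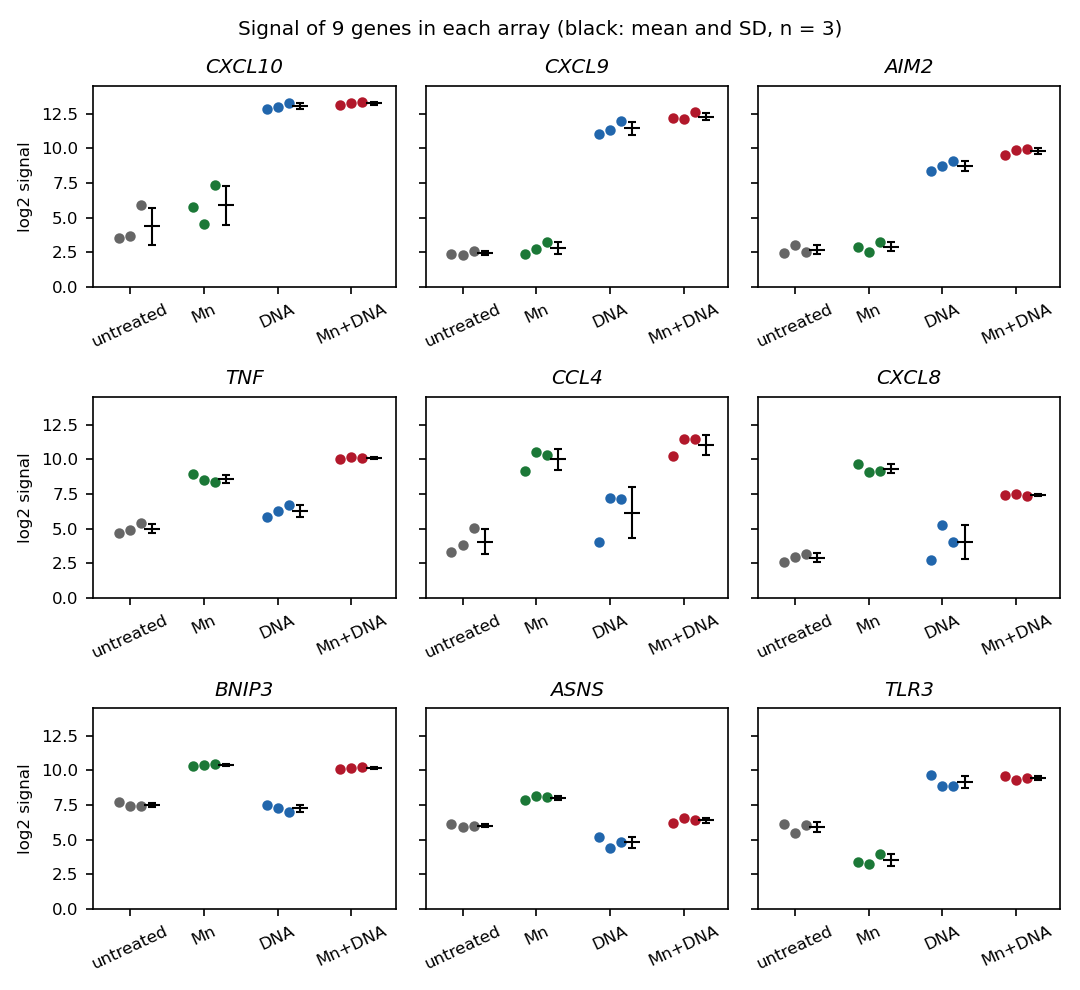
Log2 signal (y axis) of 9 genes in each of the 12 arrays by group (x axis); coloured points are the 3 arrays of a group and the black marks the mean and SD. CXCL10 averages 13.06 after DNA and 13.25 after Mn+DNA, and TNF averages 5.00 in untreated cells, 8.61 after Mn, 6.27 after DNA and 10.10 after Mn+DNA.

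Mn pretreatment before DNA was then set against DNA alone, and the genes with the largest rises included 4 chemokines. CCL4 rose by 4.93 ± 0.76 (30.5-fold), CCL3 by 4.22 ± 0.42, the cardiac and stress-inducible repeat protein ANKRD1 by 4.13 ± 0.48, CCL3L1 by 3.96 ± 0.44, TNF by 3.83 ± 0.23 (14.2-fold), TREM1 by 3.73 ± 0.26, the lymphocyte attractant CCL20 by 3.61 ± 0.24 and the AP-1 subunit FOSL1 by 3.41 ± 0.30. The largest falls were in the nuclease DNASE2B (-2.96 ± 0.34), the clock-controlled factor DBP (-2.56 ± 0.47), C1orf162 (-2.34 ± 0.21), TMEM131L (-2.11 ± 0.15), leukotriene A4 hydrolase LTA4H (-2.11 ± 0.16), the flagellin receptor TLR5 (-2.06 ± 0.27), TLR8 (-2.01 ± 0.28) and SLAMF6 (-1.96 ± 0.54). All moved the same way in 3 of 3 donors, with limma adjusted p of 0.0401 or less. In total 629 genes were higher and 823 lower, and 198 and 159 of them changed at least 2-fold. With the donor as a block 903 were higher and 1265 lower, and a fit of the compared groups alone called 546 lower. The total of 1452 was 853 without DNA replicate 1 and 962 without Mn+DNA replicate 1.

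The interferon-stimulated genes, high after DNA, had a median difference of 0.06 between Mn+DNA and DNA. LAMP3, by 1.69 on the log2 scale, was the only 1 of 38 that rose (1 adjusted over the list alone), none fell, and the list had a camera adjusted p of 0.476. CXCL10 differed by 0.19 ± 0.65 (adjusted p = 0.923), STING1 by 0.03 ± 0.15 (adjusted p = 0.946) and TBK1 by 0.25 ± 0.13 (adjusted p = 0.316). The CXCL10 arrays lay at 12.852 to 13.304 after DNA and 13.156 to 13.334 after Mn+DNA, near the highest value in the table, 13.69. A rise of CXCL10 could therefore be hidden by the ceiling, which was not tested for this gene. Its SE also takes in the untreated arrays, which ranged from 3.543 to 5.887. CGAS rose by 0.88 ± 0.25 (adjusted p = 0.0486) and HMOX1 fell by 0.78 on the log2 scale (adjusted p = 0.0144). MT2A differed by -0.26 ± 0.20 (adjusted p = 0.527) and MT1X by -0.51 ± 0.31 (adjusted p = 0.4). Of 14 guanylate-binding and interferon-gamma-inducible genes 4 rose and 1 fell (7 and 1 adjusted over the list alone). The cytokine subunit IL27 rose by 2.56 ± 0.22, ANKRD22 by 3.26 ± 0.43, CD274 by 1.21 ± 0.18 and IRF1 by 0.91 ± 0.22. This list had an adjusted p of 1.45e-05, and an adjusted p of 0.354 with an estimated correlation.

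Further lists were higher in Mn+DNA than in DNA. Cytokines and chemokines had 10 of 21 members higher (12 adjusted over the list alone), including PTGS2 by 3.09 ± 0.26, and NF-kB feedback genes had 8 of 10 (10 adjusted over the list alone), including IER3 by 2.08 ± 0.27 and TRAF1 by 2.30 ± 0.20. The stress response list had 12 of 15 higher (13 adjusted over the list alone), with DDIT4 at 2.80 ± 0.22, the ER-secreted factor MANF at 1.33 ± 0.14, the unfolded-protein factor XBP1 at 1.52 ± 0.17 and ASNS at 1.59 ± 0.18. The glycolysis and hypoxia list had 8 of 13 higher (10 adjusted over the list alone), with BNIP3 at 2.91 ± 0.14, ADM at 1.63 ± 0.15, ANKRD37 at 1.68 ± 0.23 and lactate dehydrogenase LDHA at 0.79 ± 0.11. None of these 4 lists had a lower member. Their camera adjusted p was 7.48e-12, 6.56e-13, 2.09e-15 and 2.34e-12, and 0.0196, 0.0131, 0.0394 and 0.00321 with an estimated correlation. In the p53 and apoptosis list 3 of 11 rose (3 adjusted over the list alone): PMAIP1 by 1.95 ± 0.34, the stress cytokine GDF15 by 1.94 ± 0.39 and the ribonucleotide reductase subunit RRM2B by 0.77 ± 0.16. TP53I3 differed by -0.55 ± 0.23 (adjusted p = 0.169, or 0.0113 with the donor as a block). That list had an adjusted p of 0.0042, and an adjusted p of 0.622 with an estimated correlation.

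Between Mn+DNA and Mn alone, the largest rises were again in CXCL9, CXCL11 and CXCL10. CXCL9 rose by 9.49 ± 0.25, CXCL11 by 8.28 ± 0.28, CXCL10 by 7.36 ± 0.65, the signalling adaptor STAP1 by 7.11 ± 0.24, AIM2 by 6.89 ± 0.22, HESX1 by 6.39 ± 0.36, CD38 by 6.35 ± 0.29 and the DNA helicase BRIP1 by 6.16 ± 0.24. The largest falls were VNN1 (-3.67 ± 0.42), RASSF2 (-2.68 ± 0.18), the stress ligand ULBP1 (-2.65 ± 0.25), VLDLR (-2.50 ± 0.27), HIP1 (-2.43 ± 0.29), S100A9 (-2.32 ± 0.52), PXK (-2.22 ± 0.19) and MCM6 (-2.16 ± 0.19). These moved the same way in 3 of 3 donors, with limma adjusted p of 0.00832 or less. All 38 interferon-stimulated genes rose (38 adjusted over the list alone; median 3.29), with RTP4 at 4.18 ± 0.17, SP110 at 3.29 ± 0.14, RIGI at 3.34 ± 0.14 and SAMD9 at 3.41 ± 0.15. So did 13 of 14 guanylate-binding and interferon-gamma-inducible genes (13 adjusted over the list alone), with IL27 at 3.49 ± 0.22 and GBP4 at 4.81 ± 0.36. CGAS rose by 2.24 ± 0.25, STING1 by 0.54 ± 0.15 (adjusted p = 0.0243), TBK1 by 0.48 ± 0.13 (adjusted p = 0.0272), TNF by 1.49 ± 0.23 and MT2A by 2.76 ± 0.20, while MT1X differed by 0.04 ± 0.31 (adjusted p = 0.967) and HMOX1 by 0.11 ± 0.17 (adjusted p = 0.782). In total 928 genes were higher and 1505 lower, and 409 and 294 of them changed at least 2-fold.

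Against Mn alone, 12 lists passed camera in Mn+DNA and 0 did with an estimated correlation. The interferon-stimulated and guanylate-binding lists had adjusted p of 1.7e-54 and 1.22e-19, and 0.0522 for each with an estimated correlation. Cytokines and chemokines had 8 of 21 higher and 2 lower, led by IL1RN (3.84 ± 0.26) and CCL5 (2.80 ± 0.26), and cytosolic nucleic acid sensing had 8 of 20 higher and 4 lower, led by AIM2 and TLR3 (5.88 ± 0.25). Their adjusted p was 0.00232 each, and 0.203 and 0.177 with an estimated correlation. Smaller lists called upward were MHC class II presentation (3 of 4, led by CD86 at 1.08 ± 0.11), inflammasome and pyroptosis (2 of 4, GSDMD at 1.16 ± 0.13 and PYCARD at 0.65 ± 0.18), metallothioneins and zinc transport (2 of 11, MT2A and MT1F at 1.41 ± 0.30), and p53 and apoptosis (2 of 11, MLKL at 2.42 ± 0.22 and RIPK3 at 0.86 ± 0.25). In the last list BAX differed by 0.38 ± 0.14 and PMAIP1 by 0.86 ± 0.34, with adjusted p of 0.0946 and 0.119, or 0.0297 and 0.00268 with the donor as a block, where 4 of the 11 rose. Lists called downward were oxidative stress (7 of 13, CAT at -0.99 ± 0.12 and TXNRD1 at -0.97 ± 0.15), the stress response (8 of 15 lower and 1 higher, TRIB3 at -1.74 ± 0.19 and ASNS at -1.62 ± 0.18), glycolysis and hypoxia (5 of 13 lower and 1 higher, VEGFA at -1.91 ± 0.10 and GPI at -1.01 ± 0.13) and oxidative phosphorylation (4 of 9, UQCRB at -0.72 ± 0.14 and COX4I1 at -0.43 ± 0.10). These 8 lists had adjusted p between 0.00232 and 0.047, and between 0.0743 and 0.528 with an estimated correlation. Adjusted over each list alone, the members higher and lower were 8 and 2 for cytokines, 9 and 4 for sensing, 3 and 0 for MHC class II, 2 and 0 for inflammasome, 2 and 0 for metallothioneins, 2 and 0 for p53, 0 and 7 for oxidative stress, 3 and 8 for the stress response, 1 and 8 for glycolysis, and 0 and 6 for oxidative phosphorylation.

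Cells given both treatments, set against untreated cells, had the largest number of called genes among the 6 comparisons, with 1581 higher and 2332 lower, and 671 and 767 of them changed at least 2-fold. CXCL9 rose by 9.86 ± 0.25, CXCL10 by 8.87 ± 0.65, CXCL11 by 8.56 ± 0.28, CCL8 by 7.35 ± 0.68, AIM2 by 7.11 ± 0.22, CCL4 by 7.0 ± 0.76, CD38 by 6.95 ± 0.29 and the itaconate-producing enzyme ACOD1 by 6.69 ± 0.65. GPR34 (-6.56 ± 0.75), RGS18 (-4.56 ± 0.32), MANSC4 (-4.53 ± 0.18), VNN1 (-4.52 ± 0.42), DNASE2B (-4.11 ± 0.34), HGF (-4.05 ± 0.30), TLR5 (-3.59 ± 0.27) and C1orf162 (-3.42 ± 0.21) fell most. Their limma adjusted p was 3.41e-05 or less, in 3 of 3 donors each. TNF rose by 5.11 ± 0.23, CGAS by 3.18 ± 0.25, TBK1 by 1.28 ± 0.13 and MT2A by 1.78 ± 0.20, HMOX1 fell by 0.75 on the log2 scale, and STING1 differed by 0.19 ± 0.15 (adjusted p = 0.421). MT1X differed by -0.74 ± 0.31 (adjusted p = 0.109, or 0.022 with the donor as a block).

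In that comparison 37 of 38 interferon-stimulated genes rose (38 adjusted over the list alone), with LAMP3 at 6.11 ± 0.23, and 13 of 14 guanylate-binding and interferon-gamma-inducible genes did (13 adjusted over the list alone), with IRF1 at 3.63 ± 0.22. Of the cytokines and chemokines 17 of 21 rose (18 adjusted over the list alone), with CCL5 at 6.10 ± 0.26, and 10 of 10 NF-kB feedback genes did (10 adjusted over the list alone), with TRAF1 at 4.96 ± 0.20. Of the glycolysis and hypoxia genes 6 of 13 rose (6 adjusted over the list alone), with ADM at 3.78 ± 0.15. Camera adjusted p was 5.66e-38, 1.51e-17, 3.38e-14, 6.43e-11 and 5.48e-05, and with an estimated correlation the adjusted p was 0.0558, 0.0245, 0.0244, 0.0244 and 0.0245. Like the interferon-stimulated genes, a further 6 lists were called at the preset correlation only. They were MHC class II presentation (3 of 4 higher, CD80 at 4.73 ± 0.24), the stress response (8 of 15 higher and 1 lower, ATF3 at 2.35 ± 0.19), p53 and apoptosis (6 of 11 higher and 1 lower, PMAIP1 at 3.33 ± 0.34), inflammasome and pyroptosis (3 of 4 higher and 1 lower), alternative activation markers (7 of 16 lower and 1 higher, VSIG4 at -2.76 ± 0.23) and cell cycle (10 of 23 lower and 2 higher, MCM6 at -2.88 ± 0.19). Their adjusted p was 0.0178, 0.00181, 0.00153, 0.0387, 0.0363 and 0.0133, and with an estimated correlation the adjusted p was 0.113, 0.342, 0.297, 0.163, 0.183 and 0.189. Over each list alone, 3, 8, 8, 3, 1 and 2 members were higher and 0, 1, 1, 1, 7 and 11 lower. With the donor as a block the inflammasome list had an adjusted p of 0.075, and MHC class I presentation passed at 0.0354 from 0.0859.

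The effect of DNA was then compared between cells without and with Mn, with group means from disjoint sets of arrays of the same donors. Across the 14873 genes, which are not independent replicates, the DNA effects correlated at r = 0.772 (Spearman's rho 0.530), with a slope of 0.780 for the effect in Mn-pretreated cells on that in cells without Mn. Of the genes called, 593 were higher in both comparisons where independent lists would share 59.0, 720 were lower in both against 121, and 10 were opposite. As all arrays entered 1 fit, a gene had the same SE in both comparisons, here and for the Mn effects that follow. Shared counts above those of independent lists can come from that too. The Mn effects without and with DNA correlated at r = 0.675 (rho 0.496), with a slope of 0.550. They shared 430 higher genes against 43.9 and 449 lower genes against 61.1, and 6 were opposite. Both slopes are least-squares fits, which noise in the effect without the other treatment lowers. The slopes alone therefore do not show that an effect was weaker with the other treatment.

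**Figure D3:**
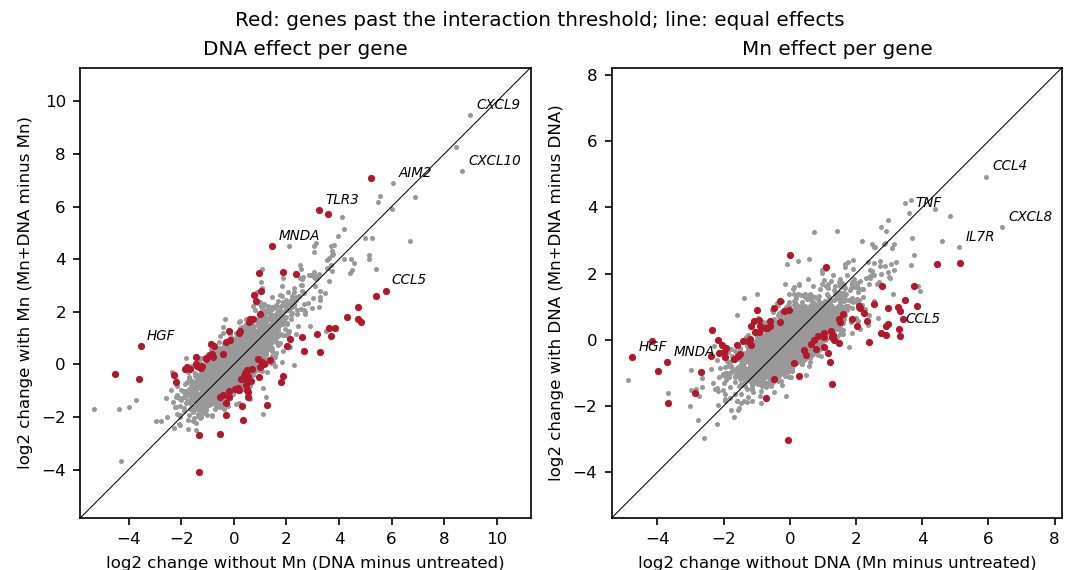
Log2 change of each of 14873 genes for DNA without Mn (x axis) and with Mn (y axis), left, and for Mn without DNA (x axis) and with DNA (y axis), right; red points are the 91 genes past the interaction threshold and the line marks equal effects. CXCL9 lies near the line on the left, at 9.0 and 9.49, while TNF lies near it on the right, at 3.61 and 3.83.

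The interaction test, which asks whether the DNA effect differed with Mn, called 41 genes with a positive and 50 with a negative value. With the donor as a block it called 109 and 129, and the 91 genes were all among these 238. Left out singly, 9 arrays lowered the 91 by over 1.5 times, to 43 without untreated replicate 2, 44 without untreated replicate 3, 43 without Mn replicate 1, 30 without Mn replicate 2, 45 without DNA replicate 2, 54 without DNA replicate 3, 47 without Mn+DNA replicate 1, 54 without Mn+DNA replicate 2 and 29 without Mn+DNA replicate 3. Without untreated replicate 1 the positive values numbered 24, and without Mn replicate 3 the negative ones 32. HGF (4.24 ± 0.42), MANSC4 (4.13 ± 0.25) and RGS18 (3.04 ± 0.45) had positive values, and each treatment alone lowered them, to group means between 2.48 and 3.70, with means of 2.05 to 3.18 in Mn+DNA. The sum of both single falls would put each of them below the lowest value in the table, 1.12. A positive value was therefore fixed by the scale for these genes. MNDA (3.03 ± 0.18) and TLR3 (2.63 ± 0.35) fell with Mn alone, and their means were 11.37 and 9.14 after DNA and 10.70 and 9.42 after Mn+DNA. IL27 (2.54 ± 0.30), SECTM1 (2.16 ± 0.34) and IQCK (1.89 ± 0.32) were also positive. Negative values were found for CCL5 (-2.97 ± 0.37), SGPP2 (-2.82 ± 0.47), the tetrahydrobiopterin enzyme GCH1 (-2.80 ± 0.48), COXFA4L3 (-2.78 ± 0.43), cholesterol 25-hydroxylase CH25H (-2.59 ± 0.52), MCOLN2 (-2.49 ± 0.24), GPR84 (-2.46 ± 0.33) and the neutrophil attractant CXCL5 (-2.45 ± 0.45). Limma adjusted p was 0.0475 or less, in 3 of 3 donors each. Because the interaction and both single-treatment effects use the untreated arrays, chance values of those arrays push a gene's single effects and its interaction in opposite directions.

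Of the lists, 3 had lower values in the interaction and none higher. Oxidative stress had 3 of 13 members lower (9 adjusted over the list alone, 6 with the donor as a block): SRXN1 (-1.48 ± 0.27), PRDX1 (-0.84 ± 0.17) and PGD (-0.77 ± 0.15). The lipid hydroperoxide reductase GPX4 differed by -0.79 ± 0.17 (adjusted p = 0.0637, or 0.0301 with the donor as a block). Glycolysis and hypoxia had 4 of 13 (4 adjusted over the list alone): VEGFA (-1.59 ± 0.14), HK2 (-0.87 ± 0.14), ADM (-1.17 ± 0.21) and LDHA (-0.81 ± 0.16). NF-kB feedback genes had 3 of 10 lower (6 lower and 1 higher adjusted over the list alone): TRAF1 (-2.14 ± 0.28), NFKB2 (-1.17 ± 0.16) and RELB (-0.97 ± 0.16). Camera adjusted p was 4.08e-07, 1.86e-06 and 2.17e-05, and with an estimated correlation the adjusted p was 0.0178, 0.0178 and 0.121. None of the 38 interferon-stimulated genes passed (1 higher and 2 lower adjusted over the list alone, 1 and 1 with the block), and that list had an adjusted p of 0.683. CXCL10 differed by -1.32 ± 0.92 (adjusted p = 0.674), TNF by 0.22 ± 0.33 (adjusted p = 0.89), CGAS by -0.06 ± 0.36 (adjusted p = 0.976) and TBK1 by -0.55 ± 0.19 (adjusted p = 0.273). STING1 (0.38 ± 0.21), MT2A (0.72 ± 0.28), MT1X (0.27 ± 0.44) and HMOX1 (0.08 ± 0.25) had adjusted p of 0.553, 0.366, 0.902 and 0.947. Phagocytosis and Fc receptors had an adjusted p of 0.0564, or 0.0095, upward, with the donor as a block. Across 14873 genes 1620 had an unadjusted p under 0.05.

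Several lists passed in no comparison at the preset correlation. Counts adjusted over the list alone follow in brackets, higher before lower. Iron handling had 0 of 11 higher and 2 lower after DNA (1 and 2), and 2 higher and 3 lower after Mn (2 and 3). With Mn the ferroxidase CP rose by 3.93 on the log2 scale, and the iron hormone HAMP and the reductase CYBRD1 fell by 1.82 and 1.83. Heat shock proteins had 2 of 8 higher after DNA (2 and 0), the near-identical pair HSPA1A and HSPA1B, and 1 higher and 1 lower after Mn (1 and 2). Cholesterol synthesis had 1 of 15 higher and 1 lower after DNA (1 and 1), and 1 and 2 after Mn (1 and 2). Cholesterol efflux and LXR targets had 3 of 12 lower after DNA (1 and 3) and 1 after Mn (0 and 0), and with the donor as a block 1 higher and 4 lower after DNA and 1 and 1 after Mn. Lysosome had 3 of 13 higher and 2 lower after DNA (3 and 2), and 1 and 1 after Mn (2 and 1). MHC class I presentation had 2 of 6 higher after DNA (2 and 0). The lists not called had adjusted p of 0.0618 to 0.992 in DNA against untreated and 0.0756 to 0.953 in Mn against untreated.

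Markers of other cell types passed as lists in none of the 6 comparisons, at the preset correlation, at an estimated one or with the block. Among 9 T cell markers IL7R alone rose, by 2.30 ± 0.44 after DNA and 5.12 ± 0.44 after Mn. Of 8 monocyte markers S100A9 (-2.03 ± 0.52) and FCN1 (-0.92 ± 0.28) fell after DNA, while after Mn CSF3R fell by 1.37 on the log2 scale and S100A12 rose by 0.43. Of 6 dendritic cell markers CCR7 rose by 3.29 ± 0.59 after DNA and 2.73 ± 0.59 after Mn, XCR1 rose by 1.06 after DNA, and CD1A fell in both. Of 6 NK cell markers 0 rose after DNA and NCAM1 rose after Mn, and of 4 B cell markers PAX5 rose after DNA and 0 after Mn. Neutrophil markers (MMP8 of 7) and platelet markers (TREML1 of 4) each had 1 lower in both comparisons. None of 5 fibroblast and endothelial markers (1 lower in each with the donor as a block) and not the 1 measured erythroid marker passed in either. Adjusted over the list alone these counts were the same, except that 2 of 8 monocyte markers were higher and 2 lower after Mn, and 2 of 5 fibroblast and endothelial markers were lower after Mn.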

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

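The tests of array floor and ceiling, of T cells and of the spread between donors were chosen only after the result was seen, and the counts over other splits of the arrays were set beforehand.

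The effect of DNA differed between cells with and without Mn in 91 genes by the interaction test. The time since Mn may differ between Mn and Mn+DNA cells, and a Mn effect that changes with time cannot be told apart from such a difference here. Positive log2 values were found for HGF (4.24), MANSC4 (4.13), RGS18 (3.04), MNDA (3.03), TLR3 (2.63), IL27 (2.54), SECTM1 (2.16), IQCK (1.89), the complement receptor VSIG4 (1.70) and the scavenger receptor MARCO (1.66). Negative values were found for CCL5 (-2.97), SGPP2 (-2.82), GCH1 (-2.80), COXFA4L3 (-2.78), CH25H (-2.59), MCOLN2 (-2.49), GPR84 (-2.46), CXCL5 (-2.45), CD80 (-2.45), CD274 (-2.26), TRAF1 (-2.14), VEGFA (-1.59), SRXN1 (-1.48), NINJ1 (-1.19), ADM (-1.17), NFKB2 (-1.17), the autophagy receptor SQSTM1 (-1.05), RELB (-0.97), HK2 (-0.87), PRDX1 (-0.84), LDHA (-0.81) and PGD (-0.77). The lists called were NF-kB feedback genes, oxidative stress, and glycolysis and hypoxia, with median log2 interactions of -0.73, -0.63 and -0.27. With an estimated correlation the NF-kB list lost its call (adjusted p = 0.121), and the other lists had an adjusted p of 0.0178 each.

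A signal close to the floor of the array may hide a further fall and so give a positive interaction. Of the 41 positive genes 10 had a Mn+DNA mean under 4, fewer than the floor was taken to need as the cause of most. A mean above 4 does not show that the sum of a gene's single falls stays above the floor. The count therefore does not decide for the remaining genes. For HGF, MANSC4 and RGS18, among the 10, that sum would lie below the lowest value in the table, 1.12. Their positive values were fixed by the floor and do not show that Mn altered their response to DNA. The floor stays open for the others of the 10. A ceiling could give negative values in the same way, and 4 of the 50 negative genes had a Mn+DNA mean above 11. The ceiling stays open for those 4, and for the other negative genes this count has the same limit as that for the floor. Of the positive genes 20 fell with both treatments alone, and of the negative ones 29 rose with both. Part of that may come from the untreated arrays that all these effects share, and a biological limit common to both treatments was not tested.

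For the interaction, 100 of the 200 possible splits were drawn, and 5 of them, the real one included, called at least 91 genes. The highest other count was 2996, in the split that exchanged the DNA and Mn+DNA labels. There the contrast adds the Mn effects in place of taking their difference, which is a structure of the samples. The others called 573, 468 and 274. Splits that exchange some arrays between cells with and without Mn carry part of the Mn effects as well, so these splits are no clean measure of chance for an interaction. Their count does not exclude chance, and it does not show it either. Of the 18 drawn splits that kept the 3 donors apart in every group as the real one does, 3 called at least as many, and the highest of the others was again 2996.

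For the other comparisons 10 splits are too few for a share under 0.05. The real split was the only 1 of 10 to reach its count in each. DNA against untreated called 2142 genes and the highest other split 0, Mn against untreated 2143 and 1, Mn+DNA against DNA 1452 and 1, Mn+DNA against Mn 2433 and 0, and Mn+DNA against untreated 3913 and 0. Of the 10 splits 4 parted all 3 donor pairs, and among these the highest other count was 0 in all 5 comparisons. Each other split mixed arrays of both groups, so a treatment effect entered its spread and lowered its count. The low counts are therefore no clean measure of chance.

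IL7R, a marker of T cells, and CCR7, a marker of mature dendritic cells that T cells also carry, rose with Mn. T cells in the Mn cultures could bring both transcripts. The other 8 measured T cell markers had a median log2 change of -0.043 (interval -0.213 to 0.139), with the highest at 0.143 and no group mean above 4.80, which argues against T cells as the source. The interval comes from resampling these 8 markers and holds no spread between donors. Spread between donors was looked at through the ratio of each change to its SE. For IL7R the change was 11.7 times its SE and of 1 sign in 3 of 3 donors. IL7R had been named for a large change past the threshold in 3 of 3 donors, so this ratio is no independent test of donor spread. CCR7 also rose in 3 of 3 donors (adjusted p = 0.00827), and its ratio of 4.595 missed the bound of 5 set for both, which is stricter than the test it passed. Induction in the macrophages themselves is a hypothesis that these values do not settle.

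Some of the 37519 array rows without a gene name here also passed the threshold, 1811 in DNA against untreated, 1452 in Mn against untreated, 793 in Mn+DNA against DNA, 2018 in Mn+DNA against Mn, 3503 in Mn+DNA against untreated and 31 in the interaction. They are outside the comparisons of named genes, and what they measure was not analysed here.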

How the results depend on the processing

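Fitting every row and a second quantile normalization of the gene lists were chosen only after the result was seen, and the other tests were set beforehand. Of 321 results for named genes, 280 were past the threshold, and none reversed under any setting. Part of this was fixed by the choice of genes and by the design. Genes with the largest changes were named only if they moved the same way in 3 of 3 donors, so leaving out a donor could not reverse them. The block does not alter the log2 changes when every group holds the same donors. With the donor as a block 9 more passed, which stand in the text beside their results, and none was lost. A second quantile normalization took the call from 5 results, and array weights and a test of every named row from 3 each. The compared groups alone and the trend and robust settings took it from 2 each, and the mean of a gene's rows from 1. Leaving out 1 array took the call from 29 results at least once, and leaving out a donor from 63. Sign changes of values past the threshold in neither fit were only counted, and there were 22 and 10 of them. Of 51 list calls 36 were lost with an estimated correlation. The inflammasome list in Mn+DNA against untreated was lost with the block (adjusted p = 0.075), with median centring (0.0539) and without replicate number 3 (0.0757). In Mn+DNA against Mn the metallothionein list was lost with a second quantile normalization (0.0599) and without replicate numbers 1 and 3 (0.125 and 0.115), and the p53 list without number 2 (0.0631). Alternative activation in DNA against untreated was lost without number 3 (0.0601). Beside their results stand the other list calls the block changed and the printed list totals it moved by over 1.5 times. Where only 1 direction moved by that much, the block added 1 higher member after DNA to iron handling, the stress response, cholesterol synthesis and alternative activation. It also added 1 higher stress gene in Mn+DNA against Mn, and 1 lower monocyte and 1 higher dendritic cell marker after Mn. Of the totals over all genes it moved only that of the interaction by over 1.5 times, and of the counts in 1 direction also the lower genes of Mn+DNA against DNA, from 823 to 1265.

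With every row tested, named or not, the counts were 3579 in DNA against untreated, 4070 in Mn+DNA against Mn and 7003 in Mn+DNA against untreated, where more rows were tested. The higher ones in Mn against untreated then numbered 1613, and the interaction had 27 positive values. With an estimated correlation the called lists went from 12 to 2 in DNA against untreated, 7 to 3 in Mn against untreated, 12 to 0 in Mn+DNA against Mn and 11 to 4 in Mn+DNA against untreated. The 91 genes of the interaction became 238 with the replicate block and 139 with trend and robust settings. The block left the log2 changes unaltered, so its added calls came from the error estimate, out of which it takes donor differences. Why the trend and robust settings added calls was not tested.

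Leaving out an array or a donor gave 929 to 2150 genes in DNA against untreated, 980 to 2112 in Mn against untreated, 431 to 1428 in Mn+DNA against DNA, 1099 to 2419 in Mn+DNA against Mn and 7 to 86 in the interaction. Fewer arrays entered these fits. Single arrays lowered Mn+DNA against DNA to 853 (without DNA replicate 1) and 962 (without Mn+DNA replicate 1). In the interaction they lowered the count to 43 and 44 (without untreated replicates 2 and 3), 43 and 30 (Mn replicates 1 and 2), 45 and 54 (DNA replicates 2 and 3), and 47, 54 and 29 (Mn+DNA replicates 1, 2 and 3). Where the total moved by less, the lower genes of DNA against untreated fell to 772 without DNA replicate 3 and to 784 without replicate number 1, those of Mn+DNA against Mn to 930 without number 1, and those of Mn+DNA against DNA to 546 in a fit of the compared groups alone. Without untreated replicate 1 the interaction had 24 positive values, and without Mn replicate 3 it had 32 negative ones. Without replicate numbers 1, 2 and 3 its total was 15, 7 and 10. RMA values carry no background level, so whether a dim gene was detected is unknown. The filter on dim genes left 8078 genes.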

Other observations

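The gene families below, and the tests of ceiling and of donors for the interferon-stimulated genes, were chosen only after the result was seen, as was the ATF4 test in Mn+DNA against DNA. The ATF4 tests with Mn alone and DNA alone and the HIF-1 test with Mn alone were written before their genes were looked at. Their lists were drawn up once the results of the fixed lists were known. For the remaining comparisons of these lists no prediction was written. Intervals of medians come from resampling the genes of a list as if they were independent, so they hold no spread between donors.

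Of 17 gene families looked at and 11 tested, none was called with an estimated correlation. Of 23 dual-specificity phosphatases, some of which switch off MAP kinases, 10 rose and 2 fell with Mn (11 and 2 after centring the arrays). DUSP1 rose by 2.72 ± 0.17, DUSP5 by 2.44 ± 0.31 and DUSP14 by 2.03 ± 0.21. Of 7 measured FOS and JUN transcription factors 4 rose and none fell, with FOSL1 at 2.76 ± 0.30 and FOSL2 at 1.61 ± 0.16. Of 10 Toll-like receptors 4 fell and 1 rose with Mn. The RNA sensors TLR3 (-2.35 ± 0.25), TLR7 (-3.69 ± 0.60) and TLR8 (-3.01 ± 0.28) and the flagellin receptor TLR5 (-1.53 ± 0.27) fell, and TLR1 rose by 0.78 ± 0.14. Camera adjusted p over the 11 families was 0.00306, 0.000311 and 0.0466, and with an estimated correlation the adjusted p was 0.372, 0.234 and 0.372.

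Before DNA, Mn left 6 of the phosphatases higher and 1 lower than DNA alone (6 and 2 after centring), and 3 of the FOS and JUN factors higher (adjusted p of 0.002 and 0.000178; adjusted p of 0.262 and 0.103 with an estimated correlation). Of 11 circadian clock genes 6 fell and none rose in Mn+DNA against Mn alone: NPAS2 (-1.20 ± 0.21), PER3 (-1.0 ± 0.13), CRY1 (-0.92 ± 0.14), PER1 (-0.82 ± 0.23), PER2 (-0.80 ± 0.16) and CLOCK (-0.72 ± 0.10). That family had an adjusted p of 0.000356, and an adjusted p of 0.0527 with an estimated correlation. Of 46 interleukins and their receptors, some also on the fixed lists, 5 were higher and 1 lower in Mn+DNA against DNA, 8 and 1 against Mn, and 11 and 2 against untreated. Their adjusted p was 0.0145, 0.0044 and 0.00292, and with an estimated correlation the adjusted p was 0.103, 0.0527 and 0.0668. Against untreated, 5 FOS and JUN factors were higher in Mn+DNA (4 after a second quantile normalization), with an adjusted p of 0.00292, and an adjusted p of 0.251 with an estimated correlation. In the interaction 1 Toll-like receptor, TLR3, was higher and 1 clock gene, PER2, lower. Each of these families had an adjusted p of 0.00544, and with an estimated correlation the adjusted p was 0.434 and 0.307.

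One hypothesis is that ATF4, a transcription factor of the integrated stress response, may be more active with Mn and less active with DNA. Of 28 further ATF4 targets 19 were measured. With Mn 10 rose and none fell, with a median of 0.583 (interval 0.211 to 0.768; camera p = 5.55e-09, and p = 0.0323 with an estimated correlation). With DNA 10 fell and none rose, with a median of -0.493 (interval -0.696 to -0.025; p = 7.12e-06, and p = 0.0816 with an estimated correlation). The aminoacyl-tRNA synthetases GARS1 (1.17 ± 0.13 and -0.49 ± 0.13) and IARS1 (0.77 ± 0.12 and -1.02 ± 0.12) and the serine enzyme PSPH (0.62 ± 0.15 and -1.31 ± 0.15) moved both ways. In Mn+DNA against Mn 15 fell and none rose, with a median of -0.995 (p = 1.8e-12, and p = 0.0141 with an estimated correlation). The hypothesis stays open for Mn before DNA. There 12 of 15 genes of the fixed stress list rose, with a median of 1.33, but only 4 of the 19 further targets did. Their median was 0.126 (interval -0.143 to 0.459; p = 0.0465, and p = 0.403 with an estimated correlation), an interval that holds both 0 and the 0.3 a rise was taken to need. The interaction had a median of -0.434 with no single target called (p = 7.59e-08, and p = 0.0442 with an estimated correlation). In Mn+DNA against untreated 1 rose and 8 fell, with a median of -0.264 (p = 0.0345, and p = 0.376 with an estimated correlation). These values bear on transcripts, and other regulators of the same genes were not tested.

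A second hypothesis is that HIF-1, the hypoxia-inducible factor, may be more active with Mn. Of 28 further HIF-1 targets 15 were measured, and 7 rose and 1, MXI1, fell with Mn, with a median of 0.491 (interval 0.168 to 0.85; p = 1.49e-05, and p = 0.0017 with an estimated correlation). TMEM45A rose by 3.06 ± 0.30, HILPDA by 1.18 ± 0.22 and ERO1A by 1.06 ± 0.11. In Mn+DNA 6 rose and 1 fell against DNA, with a median of 0.394 (p = 1.89e-05, and p = 0.00183 with an estimated correlation), 5 fell against Mn (median -0.269; camera p = 0.0359, and p = 0.0554 with an estimated correlation), and 5 rose and 2 fell against untreated (median 0.337; camera p = 0.0286, and p = 0.0476). After DNA alone 3 of the 15 fell, with a median of -0.152 and a camera p of 0.205, or 0.213 with an estimated correlation. The interaction median was -0.019, with a p of 0.319 at either correlation. HIF-1 protein, oxygen and cell density were not measured here, so a change in any of these stays open.

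The interferon-stimulated genes had a median difference of 0.06 between Mn+DNA and DNA, and a ceiling of the array could hide a rise. The 17 members with a DNA mean under 10 had a median of 0.128 (interval -0.075 to 0.221), below the 0.3 that a hidden rise was taken to need. Donors' medians lay between -0.013 and 0.093. All lie under 0.3 by more than their range, which argues against donor spread hiding a rise of that size. Their differing direction was also set as a sign of such spread, but medians around 0 differ in direction with no change at all, so it decides nothing. A ceiling for the 21 brighter members stays open, as does a response already complete 24 h after transfection, which a single time point does not test.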
